A study of Mus musculus with 4 samples.

How the data were processed

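RNA sequencing libraries of mouse embryonic stem cells were compared between the parental E14 line and a derived line in which the endogenous p300 protein carries monomeric enhanced green fluorescent protein at its N-terminus. Per the labels, each line had 2 biological replicates. Cells were grown in serum and leukemia inhibitory factor on gelatin, RNA was taken up in Trizol, and libraries were made from total RNA with an Illumina TruSeq RNA kit. The labels do not name a kit that marks the strand.

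Each deposited table holds raw counts of reads per gene, which the authors produced with the STAR aligner. The submitters' processing notes name Trim Galore, STAR 2.5.3a and the mouse build GRCm38 (mm10). The gene annotation release was not given in the sources used here. Of 54838 gene identifiers, 54809 matched GENCODE M21 on GRCm38, which supplied symbols and coordinates, and the other 29 held 0.00107% of the counts. Reads in the 4 summary rows of each table were kept out of library sizes and tests. Unmapped reads made up 4.39% and 3.58% of the reads in wild-type 1 and 2, and 2.58% and 2.38% in knock-in 1 and 2. Multimapping reads made up 3.80% to 4.46%, reads outside annotated features 2.23% to 3.67%, and reads ambiguous between genes 5.96% to 6.38%. The strand-specific columns split evenly (50.2% to 50.5% in the reverse-strand column), so the unstranded column was used. Reads from a gene and an antisense or overlapping partner therefore cannot be told apart in these counts, and reads that fit several copies of a gene family were not assigned.

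Counts assigned to genes totalled 26553998 and 21791128 in wild-type 1 and 2, and 25266051 and 18946731 in knock-in 1 and 2. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, the filterByExpr low-count filter (minimum count 10), the quasi-likelihood F test and Benjamini-Hochberg adjustment over 15191 genes, with a threshold of 0.05. The model held genotype alone and all 4 libraries. Expression is given as TMM-scaled CPM (counts relative to library size), and fold changes are log2 of knock-in over wild-type. The standard error was taken as the absolute log2 fold change divided by the square root of F. Gene lists and whole chromosomes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 5 tested members and chromosomes with at least 50 tested genes, and again with an estimated correlation. The estimated form has little power with 4 libraries, since it rests on the few residual degrees of freedom. A call that does not hold there is not thereby refuted. The self-contained fry test was an alternative for the lists.

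The design, the 32 gene lists, the naming rule and the other settings to be tried were fixed before the data were examined. The named genes were Ep300, Crebbp, Pou5f1, Sox2, Nanog, Klf4 and Esrrb in every case. The rule added up to 12 genes per direction with the largest fold change among those past the threshold, with a mean CPM of at least 1, no overlap between the groups and a symbol that is not a model name of the form Gm or Rik. It further added up to 4 members per list past the threshold or, where none passed, the 2 members with the highest mean CPM. Members of lists without a change were summarised together.

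The other settings were DESeq2 size factors, no low-count filter, a stricter filter, leaving out each library, the replicate number as a block, single-strand counts, DESeq2 1.42.0, limma-voom, a minimum-fold test (glmTreat, 1.5-fold) and other set tests. Leaving out a library leaves a lone one in its group, so the spread in such a fit comes from the other group's pair alone. After the data were seen, a correction for GC content was added. Each library's log2 CPM deviation from the mean of the libraries was fitted by a natural spline (5 degrees of freedom) on transcript GC content, and the fit was used as an offset. It was also run with exon length, with the block and without each library, and a crossed pairing of the replicate numbers and an estimated correlation without each library were added.

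The procedure was tested on simulated counts of the knock-in and wild-type comparison with 220 planted changes: 100 genes changed 2-fold, 100 changed 4-fold and a list of 20 raised 1.5-fold. Without a GC trend, among 14847 genes tested, 75% of the 2-fold and 100% of the 4-fold changes and 5 genes of the list were recovered, with 14 false calls among 194. With a GC trend like that of the libraries, and among 14843 genes, 80% of the 2-fold changes and 8 genes of the list were recovered without the GC correction, with 4 false calls among 192 and 1 list called in which no change was planted. With the GC correction 97% of the 2-fold changes and 14 genes of the list were recovered, with 8 false calls among 219 and 0 such lists. All 4-fold changes were recovered either way. The common dispersion was 0.0228 without and 0.0105 with the correction, against 0.0237 and 0.0106 in the data. Counts with a GC trend were drawn with the dispersions of the GC-corrected fit and a trend from the same spline that the correction fits. The likeness of these dispersions to the data was thus built in, and the recovery with the correction holds only for a trend of that form. Each gene had the same dispersion in all libraries, so the unequal spread of the replicate pairs was not simulated. Each library was counted as its own sample, since the labels give biological replicates. The counts of the replicate libraries differed beyond sampling noise (chi-square per degree of freedom 48.8 for the wild-type pair and 6.15 for the knock-in pair). That excess does not by itself show separate cultures.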

Results

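Gene expression was measured by RNA sequencing in E14 mouse embryonic stem cells (E14Tg2a.4, strain 129/Ola) and in the knock-in line MLC460. In that line, made with CRISPR/Cas9, a green fluorescent protein is fused to p300, a histone acetyltransferase that acts as a transcriptional coactivator. There were 2 wild-type and 2 knock-in libraries, with 18946731 to 26553998 counts assigned to genes in each. The comparison of the lines asks how far expression in the tagged line differs from that in its parent. Only 1 knock-in line was sampled, so differences between the lines include any that arose when the line was derived.

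The transcript of the tagged gene did not differ detectably between the lines. Ep300 (ENSMUSG00000055024, GRCm38 chromosome 15, 81585351 to 81652077) had 210 ± 0.41 CPM in wild-type and 196 ± 20.9 CPM in knock-in cells (SD, n = 2 each). Its log2 fold change was -0.10 (SE 0.15, 95% interval -0.44 to 0.23, edgeR adjusted p = 0.804). Its paralog Crebbp (chromosome 16, 4081328 to 4213997) had 54.3 ± 5.72 and 58.3 ± 6.93 CPM, a log2 fold change of 0.10 (SE 0.17, edgeR adjusted p = 0.835). These counts cover the whole gene and do not separate a tagged from an untagged transcript.

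With all libraries, transcripts of the core pluripotency factors also showed no change past the threshold. Pou5f1, which encodes OCT4, had 557 ± 146 CPM in wild-type and 503 ± 57.2 CPM in knock-in cells (SD, n = 2 each), a log2 fold change of -0.15 (SE 0.19, edgeR adjusted p = 0.780). Without wild-type 1 its log2 fold change was -0.39, but the lone wild-type library left, wild-type 2, deviated with GC content, as described with the count of changed genes. Without wild-type 2 the value for Pou5f1 was 0.13, and it was also positive with the GC correction. The log2 fold change was -0.0010 (SE 0.14) for Sox2, -0.075 (SE 0.14) for Nanog and 0.14 (SE 0.15) for Esrrb, a regulator of naive pluripotency. Klf4 had 187 ± 1.78 CPM in wild-type and 230 ± 5.58 CPM in knock-in cells, a log2 fold change of 0.30 (SE 0.14) that did not pass with all libraries (edgeR adjusted p = 0.466) and was 0.29 without wild-type 1. As sets, neither the core list (15 genes tested, median log2 fold change 0.11, camera adjusted p = 0.126) nor the naive list (17 genes, median 0.11, adjusted p = 0.142) passed. Both passed as higher without wild-type 2 (adjusted p = 0.00899 and 0.0165) and with the GC correction described with the count of changed genes (0.0337 and 0.04997), and neither with an estimated correlation (adjusted p = 0.705 each).

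Between the lines, 10 of 15191 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1 higher and 9 lower in knock-in cells, and all 10 differed by more than 2-fold. The gene that rose was Grb10, an imprinted gene for an adaptor protein that restrains insulin and growth factor signalling (chromosome 11, 11930508 to 12038683). It went from 113 ± 7.79 CPM in wild-type to 591 ± 4.00 CPM in knock-in cells (SD, n = 2 each), a log2 fold change of 2.39 (SE 0.15, adjusted p = 0.000770). Mest, a paternally expressed imprinted gene (chromosome 6, 30723547 to 30748465), fell from 47.7 ± 9.40 to 9.32 ± 1.22 CPM, a log2 fold change of -2.35 (SE 0.21, adjusted p = 0.00906). Plagl1, a paternally expressed gene for a zinc finger transcription factor (chromosome 10, 13060504 to 13131694), fell from 9.97 ± 2.29 to 1.77 ± 0.068 CPM, a log2 fold change of -2.49 (SE 0.28, adjusted p = 0.0204).

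The X-linked homeobox genes Rhox5 (chromosome X, 37804842 to 37808876) and Rhox13 (chromosome X, 38121219 to 38129967) fell, with log2 fold changes of -1.97 (SE 0.21) and -2.02 (SE 0.27). They belong to a family of related genes, so the assignment of reads among its members is uncertain. Ddr2, which encodes a collagen receptor (chromosome 1, 169972307 to 170110762), fell from 33.0 ± 2.46 to 10.7 ± 0.59 CPM (log2 fold change -1.62, SE 0.18). The citrate transporter gene Slc13a5 (chromosome 11, 72241989 to 72267222), the keratin gene Krt19 (chromosome 11, 100140810 to 100148665) and the cyclin D2 gene Ccnd2 (chromosome 6, 127125162 to 127152193) had log2 fold changes of -1.47 (SE 0.19), -1.59 (SE 0.21) and -1.48 (SE 0.20). The remaining gene, Gm13128 (chromosome 4, 144330249 to 144333465), falls outside the naming rule and was named after its values were seen. Its log2 fold change was -2.36 (SE 0.27). Slc13a5 and Ccnd2 lost their calls without knock-in 1 (adjusted p = 0.129 and 0.139), and Slc13a5, Ccnd2 and Krt19 without knock-in 2 (0.0678, 0.0678 and 0.103).

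**Figure D1:**
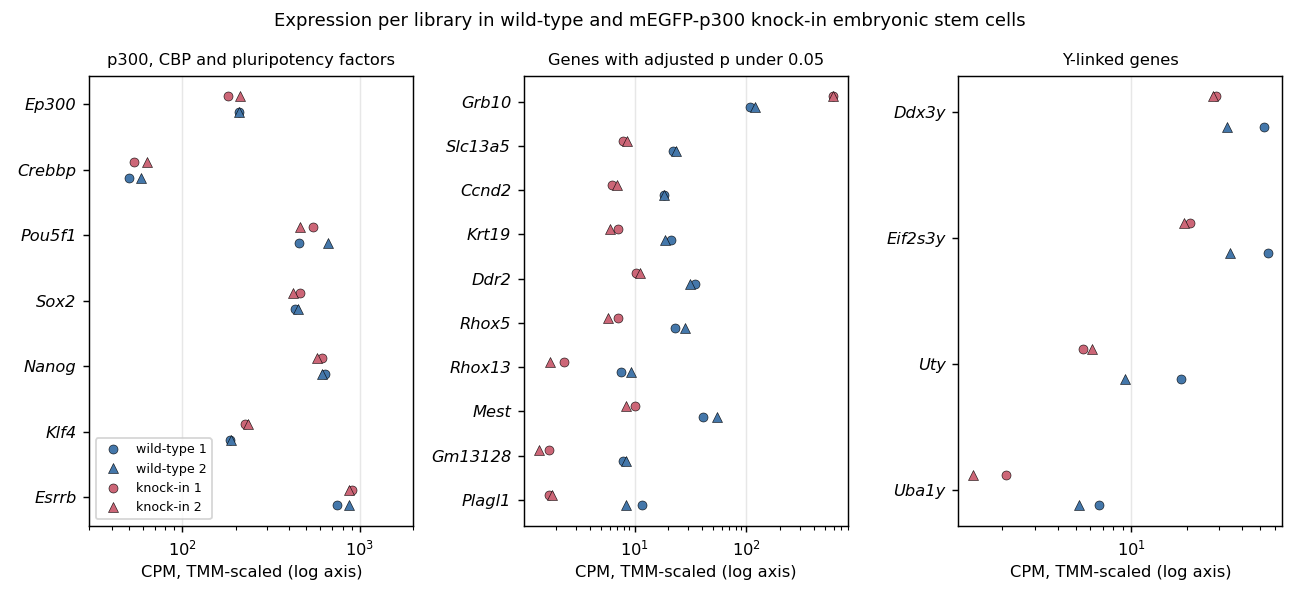
TMM-scaled CPM (log axis) of each library for p300, CBP and pluripotency factors (left), the 10 genes past an adjusted p of 0.05 (centre) and 4 Y-linked genes (right), with wild-type in blue, knock-in in red, replicate 1 as circles and replicate 2 as triangles. Grb10 lies at 107 and 118 CPM in the wild-type and at 589 and 594 CPM in the knock-in libraries, and the 4 Y-linked genes drawn lie lower in both knock-in libraries than in either wild-type library.

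How many genes passed depended strongly on which libraries were used. A fit without a library takes its spread from the other group's pair alone. The knock-in pair was the more alike (chi-square per degree of freedom 6.15, against 48.8 for the wild-type pair). The p-values of such a fit, and its count of genes passing, therefore hold no spread for the group of the lone library. The count was 5015 without wild-type 1, 711 without wild-type 2, 17 without knock-in 1 and 16 without knock-in 2, against 10 with all libraries. Wild-type 2 stood apart from the rest: among 8951 genes of at least 10 CPM, 148 differed over 2-fold between the wild-type libraries and 1 between the knock-in libraries, while 22 did between wild-type 1 and knock-in 2. Its deviation from the other libraries followed transcript GC content across genes (Spearman rho = 0.79, genes not being independent replicates), and 0.589% of its counts were mitochondrial against 1.04% to 1.27% in the others. With the GC correction, added after the data were seen, 176 genes passed, 41 higher and 135 lower, among them all 10 named above. Without the GC correction, 1662 genes had an unadjusted p under 0.05, 538 higher and 1124 lower, against 2497 with it. Both knock-in libraries lay on the same side of both wild-type libraries in 47.4% of tested genes without and 49.2% with the correction. That share would be 33.3% if all 4 libraries were interchangeable. The wild-type pair spread more than the knock-in pair, which raises the share even without a difference between the lines. The excess over 33.3% therefore does not by itself show such a difference.

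**Figure D2:**
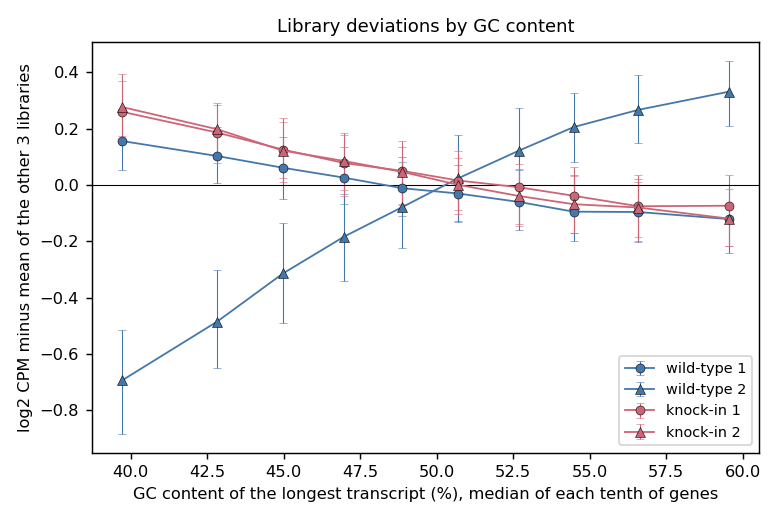
Median deviation of each library's log2 CPM from the mean of the other 3 libraries, for genes grouped into 10 equal groups by the GC content (percent) of their longest transcript, with bars spanning the quartiles. Wild-type 2 is low at low GC content and high at high GC content (Spearman rho 0.79 across genes), while the opposite runs of the others come with having wild-type 2 in their mean, since at most 1.98% of their variance followed GC content when they were compared among themselves.

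Imprinted genes, which are expressed mainly from the copy of 1 parent, held 3 of the 10 calls. Of 27 tested imprinted genes, Grb10 rose, Mest and Plagl1 fell and 24 did not pass over all genes, while 4 were higher and 8 lower when adjusted over the list alone. With the GC correction 2 of the 27 passed as higher and 4 as lower over all genes, against 176 of all 15191 genes tested. More members passed without wild-type 1 or without wild-type 2, but so did far more of all genes, above all without wild-type 1. The list as a set did not pass (median log2 fold change -0.090, camera adjusted p = 0.160). With the GC correction it passed as lower (median -0.20, camera adjusted p = 0.0106), though not with an estimated correlation (adjusted p = 0.398) or when wild-type 1, wild-type 2 or knock-in 1 was also left out (0.0667, 0.0519 and 0.0694).

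The 4 tested members of the Y-linked list were each lower in both knock-in libraries than in either wild-type library. Eif2s3y (chromosome Y, 1010543 to 1028847), a translation initiation factor gene, had 44.5 ± 14.7 CPM in wild-type and 20.02 ± 1.13 CPM in knock-in cells (SD, n = 2 each), a log2 fold change of -1.15 (SE 0.23, edgeR adjusted p = 0.149). The log2 fold change was -1.76 (SE 0.30) for Uba1y, -1.26 (SE 0.32) for Uty and -0.59 (SE 0.22) for the RNA helicase gene Ddx3y. With all libraries none passed over all genes, and all 4 did when adjusted over the list alone. The values depended on the wild-type library used. Without wild-type 1 the log2 fold change was -0.76 for Eif2s3y, -1.56 for Uba1y, -0.67 for Uty and -0.22 for Ddx3y. Without wild-type 2 it was -1.47 for Eif2s3y, -1.93 for Uba1y, -1.68 for Uty and -0.90 for Ddx3y, and without knock-in 1 it was -2.11 for Uba1y. With the GC correction all 4 passed over all genes (edgeR adjusted p = 7.62e-05 to 0.00825). A further tested gene on chromosome Y, Gm47283 (90784738 to 90816464), named after its values were seen, did not follow them. Whether it lies in the region that the X and Y chromosomes share was not examined. It had 81.2 ± 23.6 CPM in wild-type and 77.1 ± 9.87 CPM in knock-in cells, a log2 fold change of -0.075 (SE 0.21, edgeR adjusted p = 0.908), with -0.35 without wild-type 1 and 0.24 without wild-type 2. Wild-type 2 lay between wild-type 1 and the knock-in libraries for the 4 list members, at 34.1 CPM for Eif2s3y against 54.9 in wild-type 1.

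Of 31 gene lists tested as sets, 5 passed a camera adjusted p of 0.05, and none of these calls held with an estimated correlation (adjusted p = 0.705 for each). With 4 libraries that form of the test has little power, so it leaves these calls undecided. Its estimated correlation was 0.288 for the 2-cell-like list, 0.200 for the fibroblast and feeder list and 0.092 for the cell cycle list. These lie above the preset 0.01, and if they hold, the preset p-values of those lists are too small. The estimate was -0.049 for the endoderm list and -0.023 for the hypoxia and glycolysis list. In the fry test none of the 5 passed (adjusted p = 0.0873 to 0.276). The primitive and definitive endoderm list was lower in knock-in cells (15 genes, median log2 fold change -0.40, camera adjusted p = 0.00106). None of its members passed over all genes and 5 were lower when adjusted over the list alone, among them the basement membrane collagens Col4a1 (-1.10, SE 0.15) and Col4a2 (-1.23, SE 0.17), and Lama1, Amn and Hnf4a, all named after their values were seen. Its most abundant members went apart, with log2 fold changes of 0.40 (SE 0.17) for Apoe and -0.40 (SE 0.15) for Sparc. Without wild-type 1 or without wild-type 2 the 5 lower members passed over all genes, Sparc passed as lower without wild-type 1 (-0.48, edgeR adjusted p = 5.81e-05) and Apoe as higher without wild-type 2 (0.62, adjusted p = 7.15e-06). The fibroblast and feeder list was lower (9 genes, median -0.57, camera adjusted p = 0.00278), with Pdgfrb alone lower when adjusted over the list alone. More of its members passed without wild-type 1, but so did far more of all genes. After accounting for GC content, wild-type 2 lay above the other 3 libraries for this list (median log2 difference 0.321, 8 of 9 genes). Those 3 include both knock-in libraries, and all 9 genes had negative log2 fold changes, so this value holds part of the difference between the lines. Without wild-type 2 the list still passed as lower (median -0.48, camera adjusted p = 0.0405, or adjusted p = 0.705 with an estimated correlation), and with the GC correction added it did not (-0.39, adjusted p = 0.0519). Its most abundant members, Fn1 and Vim, had log2 fold changes of -0.098 (SE 0.16) and -0.016 (SE 0.19).

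The hypoxia and glycolysis list was lower (23 genes, median -0.19, camera adjusted p = 0.0127), with Adm lower when adjusted over the list alone. Its members Gapdh and Pkm had log2 fold changes of -0.17 (SE 0.19) and -0.12 (SE 0.17). More members passed without wild-type 1 or without wild-type 2, but so did far more of all genes. The 2-cell-like list, genes of rare cells that resemble the early embryo, was higher (12 genes, median 0.42, camera adjusted p = 0.0132) with no member past the threshold either way when all libraries were used. Zscan4c (0.41, SE 0.21) and Zscan4a (0.43, SE 0.19) were its most abundant members, and the Zscan4 copies are so alike that their reads are hard to tell apart. The cell cycle list was higher (27 genes, median 0.15, camera adjusted p = 0.0278), again with no member past the threshold with all libraries, and log2 fold changes of 0.32 (SE 0.17) for Top2a and -0.025 (SE 0.17) for Mcm2. The 2-cell-like and cell cycle lists did not pass without wild-type 1 (adjusted p = 0.194 each) or without knock-in 1 (0.104 and 0.225), and the hypoxia and glycolysis list did not without knock-in 1 (0.0538). Single members moved with the wild-type library used, and wild-type 2, left alone in the fit without wild-type 1, deviated with GC content. Gapdh and Pkm had log2 fold changes of -0.40 and -0.30 without wild-type 1, and of 0.10 and 0.078 without wild-type 2. Pkm was also positive with the GC correction. Top2a, Zscan4c and Zscan4a had values of 0.56, 0.61 and 0.53 without wild-type 1, and of 0.098, 0.24 and 0.33 without wild-type 2.

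**Figure D3:**
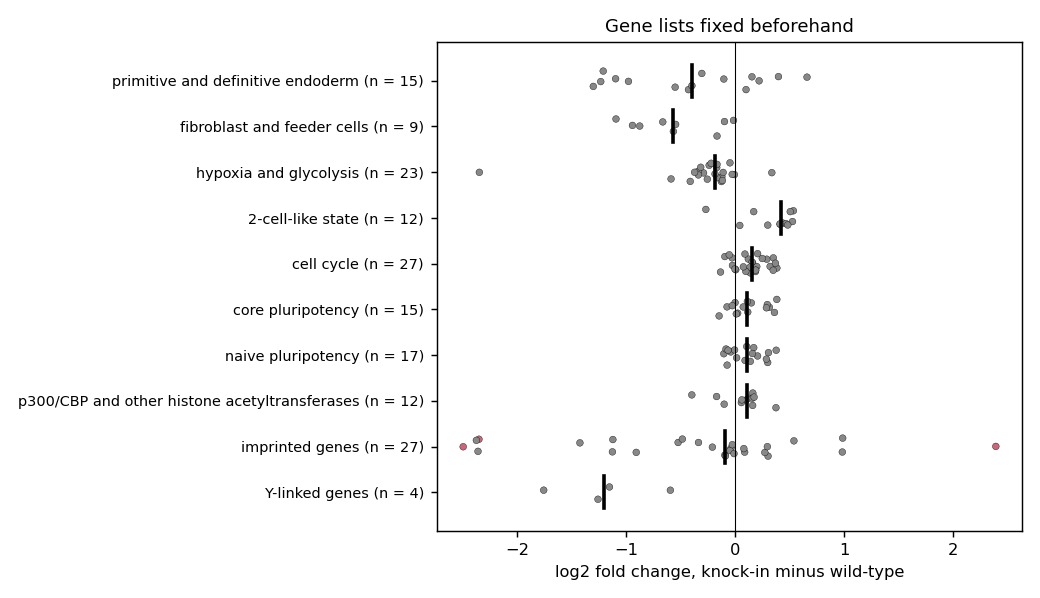
Log2 fold change (knock-in minus wild-type) of each tested member of 10 gene lists, with the median as a black bar and genes past an adjusted p of 0.05 over all genes in red. The medians are -0.40 for the endoderm list and -0.57 for the fibroblast and feeder list, and the 4 Y-linked genes lie between -1.76 and -0.59.

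The other 26 lists did not pass, and some of them depended on the libraries used. The mitochondrially encoded list (12 genes, median 0.24, adjusted p = 0.0557) passed as higher without wild-type 1 (median 0.98, adjusted p = 2.01e-21) and as lower without wild-type 2 (-0.25, adjusted p = 0.000739), and also as higher without knock-in 1 or knock-in 2 (adjusted p = 0.00866 and 0.000159). The nuclear-encoded respiratory chain list (23 genes, median -0.036, adjusted p = 0.875) passed as lower without wild-type 1 (-0.17, adjusted p = 0.0452) and as higher without wild-type 2 (0.085, adjusted p = 0.0363). Ribosomal protein genes (34 genes, median 0.059, adjusted p = 0.151) passed as higher without wild-type 2 (0.21, adjusted p = 1.11e-10) and without knock-in 2 (0.14, adjusted p = 0.0341), and the germline list as lower without wild-type 2 (-0.12, adjusted p = 0.00294). None of these calls held with an estimated correlation in the same fits (adjusted p = 0.705 to 0.928), a test that has little power with 3 libraries. With all libraries, the estimated correlation was 0.984 among the mitochondrially encoded genes (adjusted p = 0.706) and 0.541 among the ribosomal protein genes (adjusted p = 0.798). The mitochondrially encoded list also passed as higher with DESeq2 size factors (adjusted p = 0.0496), and its median was -0.065 with the GC correction (adjusted p = 0.712). Among markers of other cell types, the median log2 fold change was -0.34 for formative and primed pluripotency (adjusted p = 0.142), -0.23 for mesoderm (0.710), 0.13 for neuroectoderm (0.766), -0.17 for trophoblast (0.370) and -0.099 for the germline (0.105). Krt19 is a member of the trophoblast list and Rhox5 of the germline list. The list of p300, CBP and other histone acetyltransferases had a median of 0.11 (12 genes, adjusted p = 0.503). For cholesterol synthesis the median and mean were below 0 (-0.024 and -0.010) while the test pointed up (adjusted p = 0.946).

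None of 20 chromosomes passed as a set with camera. The lowest adjusted p was on chromosome 13 (596 genes, median log2 fold change 0.12, adjusted p = 0.0683), and chromosome 15, which carries Ep300, had a median of -0.033 (587 genes, adjusted p = 0.711). Without wild-type 1, chromosomes 3, 13, 18 and X passed as higher, but none did there with the GC correction (adjusted p = 0.958 each, with the median of chromosome 13 at 0.069 against 0.27) or with an estimated correlation (adjusted p = 0.297 each).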

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

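The GC settings, the crossed pairing and the estimated correlation without each library were chosen after the data were seen. All 10 called genes kept their sign in every setting. The call was kept by 8 without knock-in 1, 7 without knock-in 2, 9 with single-strand counts, 4 with limma-voom, 2 with the minimum-fold test and all 10 in the other settings. The count of genes changed in knock-in (10, with 1 for genes higher in knock-in and 9 for genes lower in knock-in, in this order below) was 13 with DESeq2 size factors, 11 with the stricter filter and 11 with single-strand counts. It was 354 (63 higher, 291 lower) with no filter, 123 (7, 116) with DESeq2, 4 (3 lower) with limma-voom and 2 (1 lower) with the minimum-fold test. Leaving out each library gave 16 to 5015 genes (1 to 2975 higher, 14 to 2040 lower), the highest without wild-type 1, a fit in which the lone wild-type library is assumed to vary like the knock-in libraries. GC correction gave 176 (41, 135), with length 170 (41, 129), without wild-type 1 1800 (984, 816), without wild-type 2 674 (255, 419), without knock-in 1 97 (20, 77) and without knock-in 2 121 (26, 95). With the replicate number as a block, which the labels do not tie to a shared day, 197 genes passed (46, 151), and 410 (125, 285) with GC correction added. Same-numbered libraries did not deviate together (r = -0.12 across genes), and the crossed pairing gave 509 (175, 334). Lists past the threshold (5) numbered 6 with DESeq2 size factors, 6 with the block, 6 with the crossed pairing, 9 with no filter, 8 with the stricter filter, 9 with single-strand counts, 5 to 15 leaving out each library, 14 with GC correction, 12 with length, 10 with GC correction and block, 16 with GC correction without wild-type 2, 13 with GC correction without knock-in 2, 0 with fry, run on all libraries alone, and 0 with an estimated correlation, with all libraries or without each. Chromosomes (0) numbered 1 with the stricter filter, 1 with the crossed pairing, 4 among genes with a mean of at least 10 CPM and 0 to 4 leaving out each library.

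Sign changes among named genes fell on genes that were not called, and none of the changed signs passed the threshold. For Ep300 the log2 fold change was 0.044 with GC and length correction and 0.084 with GC correction without knock-in 1. Leaving out each library gave -0.022 to 0.20 for Crebbp, -0.39 to 0.13 for Pou5f1, -0.088 to 0.067 for Sox2, -0.28 to 0.047 for Fn1, -0.26 to 0.27 for Vim, -0.40 to 0.10 for Gapdh, -0.30 to 0.078 for Pkm and -0.23 to 0.20 for Mcm2. Sox2 was 0.0058 with DESeq2 size factors and 0.0058 with DESeq2, and Vim 0.0058 with the replicate block, 0.0056 with the crossed pairing and 0.0085 with limma-voom. For Pou5f1, Sox2, Fn1, Pkm and Mcm2 in turn, GC correction gave 0.080, 0.064, 0.044, 0.10 and 0.079, with length 0.066, 0.046, 0.092, 0.12 and 0.11, and with the block 0.082, 0.062, 0.035, 0.11 and 0.092. With GC correction without wild-type 1, Sox2 was 0.020, Fn1 0.072 and Pkm 0.029. Without wild-type 2, Pou5f1 was 0.23, Sox2 0.10, Fn1 0.0092, Vim 0.32, Gapdh 0.19, Pkm 0.18 and Mcm2 0.29. Without knock-in 1, Fn1 was 0.21, Pkm 0.092 and Mcm2 0.053, and without knock-in 2, Pou5f1 was 0.20, Sox2 0.14, Vim 0.0048, Gapdh 0.012, Pkm 0.13 and Mcm2 0.12. For Gm47283, leaving out each library gave -0.35 to 0.24, GC correction 0.14, with length 0.18, with the block 0.14, without wild-type 2 0.27 and without knock-in 1 0.35. Of the 31 lists, 11 changed direction in some setting, past the threshold only for the mitochondrially encoded and the nuclear-encoded respiratory chain lists without wild-type 2, with and without GC correction. For 4 of them, not described singly, this was in 9 settings (histone deacetylases), 4 (BMP targets), 2 (Wnt targets) and 1 (stress response), and for the other 7 as follows. Leaving out each library gave medians of -0.25 to 0.98 for the mitochondrially encoded, -0.17 to 0.085 for the respiratory chain, -0.065 to 0.21 for the ribosomal, -0.49 to 0.059 for the mesoderm, -0.045 to 0.14 for the neuroectoderm and -0.083 to 0.12 for the cholesterol list. The mitochondrially encoded median was -0.065 with GC correction, -0.12 with length, -0.26 with GC correction without wild-type 2 and -0.13 without knock-in 1, and the respiratory chain median 0.16 without wild-type 2 and 0.088 without knock-in 2. With GC correction the mesoderm median was -0.12, with length -0.083, with the block -0.12, without wild-type 2 0.14 and without knock-in 2 -0.013. With GC correction without wild-type 1 the median was -0.0051 for trophoblast and -0.039 for ribosomal genes. The neuroectoderm median was -0.28 with no filter and -0.035 without wild-type 1, the ribosomal median -0.047 without knock-in 1 and the respiratory chain median 0.032 without knock-in 2, with the preset and the estimated correlation alike, and the cholesterol median -0.049 with the stricter filter, -0.0058 with GC correction without wild-type 2 and -0.024 with fry. Apart from the lower number of libraries or the larger number of genes that some settings bring, the cause was not tested.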

Other observations

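The GC correction and the tests here were chosen after the result was seen, except the marker-list test of wild-type 2 and the comparison of Y-linked genes with their X-linked partners. With the GC correction 176 genes passed in edgeR (1800 without wild-type 1, 674 without wild-type 2, 97 without knock-in 1 and 121 without knock-in 2). Higher genes included Phlda2, an imprinted growth restrainer of the placenta (log2 fold change 1.18, SE 0.13), the homeobox gene Gbx2 (0.99, SE 0.13), the deacetylase gene Sirt1 (0.85, SE 0.13), the signalling ligand Bmp4 (0.74, SE 0.11) and Spry4, a feedback inhibitor of receptor tyrosine kinase signalling (0.57, SE 0.11). Lower genes included Col4a1 (-0.89, SE 0.12) and Col4a2 (-1.02, SE 0.15), while Apoe of the same endoderm list was higher (0.64, SE 0.12). The X-linked Xlr3b was lower (-2.51, SE 0.38), and it is one of several near-identical copies. As sets, 14 lists passed with the preset and 0 with an estimated correlation. Lower were the germline, endoderm, p53 target, fibroblast and feeder, imprinted and hypoxia and glycolysis lists, and higher the cell cycle, FGF/ERK target, LIF/STAT3 target, ribosomal protein, core pluripotency, naive pluripotency, DNA methylation and Polycomb, and 2-cell-like lists.

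Wild-type 2 stood apart from the other libraries. Lower depth was argued against, since knock-in 2, the shallowest library, had only 0.246% of genes over 2-fold from wild-type 1, against 1.65% for wild-type 2. GC-related bias is a candidate explanation, as 63.1% of the variance of wild-type 2 followed GC content and at most 1.98% did among the other 3 libraries. That second bound was first set on comparisons that included wild-type 2, which fixed their outcome, and was restated after the values were seen. Another mix of cells cannot be told apart from these values, because after GC correction the largest marker-list median was 0.321 (fibroblast and feeder list, 8 of 9 genes higher), under the 0.5 set beforehand, and a small share of other cells would move few markers. That median was taken against libraries that include both knock-in ones, so it also holds part of the difference between the lines.

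Grb10 was higher and Mest and Plagl1 were lower, and GC content was argued against, since the smallest of the 3 absolute log2 fold changes after correction was 2.39. Fibroblasts in the wild-type cultures were argued against for Mest, provided that they hold more type I collagen than Mest transcript, since Col1a1 and Col1a2 together fell by 4.11% of the CPM by which Mest did (3.33% to 4.69% over the 4 pairs of a wild-type and a knock-in library), and for Grb10, since a lower share of stem cells would lower stem cell genes alike and the highest of 15 core pluripotency genes had a log2 fold change of 0.38. For Plagl1 they cannot be told apart, because the collagens fell by 19.2% of its fall (11.1% to 31.2% over the pairs), and all 9 tested fibroblast and feeder genes were lower in knock-in cells (median -0.57, and -0.43 with the GC correction, camera adjusted p = 0.00924, or adjusted p = 0.398 with an estimated correlation). One hypothesis is that methylation was gained at maternally methylated control regions in the knock-in line, which may raise Grb10 and lower Mest and Plagl1, and of 14 other such imprinted genes 11 moved in the direction it predicts, against a mean of 7.02 for random genes of like expression (one-sided p = 0.0196 from 10000 draws, which replaced an exact binomial test giving p = 0.0287). Directions were assigned from textbook knowledge after the values were seen, and genes of 1 cluster are not independent. Most of the predicted directions were down, and the imprinted list was itself lower with the GC correction, so the count partly restates that. Methylation was not measured, and whether the tag or the derivation of this line is involved stays open and untested.

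The 4 members of the Y-linked list were lower in knock-in cells, and after GC correction all passed over all genes in edgeR, with a median log2 fold change of -1.62, which argues against GC content. A loss of the Y chromosome from a share of the cells that lowers all 4 by the same factor stays open. With all libraries, the 4 log2 fold changes after GC correction were unequal (heterogeneity p = 0.00332, Cochran's Q against a chi-square distribution). That test takes the standard errors as known and so gives too small a p. Its outcome also depended on which library was left out. Ddx3y had -1.03, against -1.57 for Eif2s3y, -1.66 for Uty and -1.73 for Uba1y. Its X-linked partner Ddx3x had a mean of 788 CPM, against 35.3 for Ddx3y. How reads were assigned between such partners was not resolved, so unequal values cannot decide against an equal loss. A loss that lowers Eif2s3y, Uba1y and Uty alike also stays open (heterogeneity p = 0.840 in the same chi-square test). Ddx3y (-1.03, SE 0.13) was left out after it was seen to differ, so the likeness of the other 3 cannot count for such a loss. Gm47283, also on chromosome Y, did not go with them (0.14, SE 0.15). As a single gene with a high GC content (69.4%) it was not used to exclude a loss. Whether it lies in the region that the X and Y chromosomes share was not examined. Reads assigned to X-linked partners cannot be told apart, although 3 of the 4 partners rose by at least as many CPM as their Y-linked copy fell, the number set beforehand for that cause. The test was judged void because partners are far more abundant, and for 3 of the 4 the SD between the wild-type libraries exceeded the CPM by which the Y-linked copy fell. The rises were also taken without the GC correction, and with it none of the partners passed (edgeR adjusted p = 0.413 to 0.857).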
